A study of Homo sapiens with 4 samples.

How the data were processed

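The samples were 4 preparations of total RNA labelled as from MCF-7 cells, each hybridised to 1 Affymetrix expression array. There were 2 controls, 1 transfected with a miR-9 mimic and 1 with a miR-9* mimic. Groups and replicate numbers were taken from the sample labels, and 0 columns of the table belonged to no sample. The labels call the controls biological replicates. Nothing says that they came from separate cultures treated side by side with the mimics. For a single mimic, and for the mimics against each other, p-values therefore rest on the spread between these 2 arrays. Most of that spread is pooled over all probe sets, not taken from each one. For both mimics together p-values also use the distance between the miR-9 and miR-9* arrays.

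The deposited table holds the intensity of each probe set on a linear scale, with values from 4.18 to 21811. The submitters' processing notes name MAS5 and RMA, without a version and without saying which of them made these values. The scale was taken from the values themselves, which are not logarithms. The genome build was not given in the sources used here, so no coordinates are printed.

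The table holds 2160 probe sets. A test of its rows found that the linear mean of both mimic arrays was at least 2-fold from control 1 in all of them (smallest fold 2.00009) and that the highest signal among control 1 and the mimics was never below 100.1. The sources used here do not state this filter. A transcript lowered by 1 mimic alone cannot meet it, and comparisons with control 1 are conditioned on it. Comparisons of the mimics with control 2 are conditioned on it in part, through the mimic values. Other probe sets of the array were not analysed here. Gene symbols came from the platform annotation paired with the probe sets and were updated by Entrez identifier against a RefSeq gene table, which altered 0 symbols. There were 1964 probe sets with 1 symbol (1431 genes), 90 with several and 106 with none; the last 2 kinds were named for no gene. A gene with several probe sets was represented by the one with the highest mean over all arrays.

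Signals were analysed as log2(signal + 1), without further scaling. Models were fitted with limma 3.58.1 in R 4.3.3. The comparisons of each mimic with control and of the mimics with each other came from a fit with 1 coefficient per group. Its single residual degree of freedom comes from the 2 controls, and the lone mimic arrays are assumed to vary like them. The comparison of both mimics with control came from a fit with 2 groups and 2 residual degrees of freedom. Of these, 1 comes from taking the miR-9 and miR-9* arrays, which had different treatments, as replicates. Empirical Bayes moderation was used, with Benjamini-Hochberg adjustment over all probe sets and a threshold of 0.05. Errors given after ± are standard errors from these fits, with a median of 1.07 log2 units for 1 mimic against control. The prior pooled over probe sets had 5.61 degrees of freedom there, against 1 from the controls. These errors are therefore largely a pooled value: IFIT1 had a control standard deviation of 0.054 log2 units and an error of 1.03 with miR-9. For both mimics together the median error was 0.45, in part because the 2 mimic arrays lie close together. Differences understate the fold of transcripts near the lowest signals, since 1 unit was added before the logarithm.

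The fits were tested on simulated data of 2160 probe sets, 200 of them altered. The simulated spread was that between the controls after moderation, which draws each probe set toward a pooled value. It therefore varied less between probe sets than the spread seen. For miR-9 against control, 0 of the 200 were recovered at 2-fold, 2 at 4-fold and 0 at 16-fold, with 3, 4 and 0 unaltered probe sets called beside them. For both mimics against control, 0, 4 and 154 were recovered, with 0, 3 and 3 unaltered ones called. With a spread 10 times smaller all 200 were recovered in both comparisons at each size, beside 5 to 23 unaltered ones. At this spread a count of 0 therefore excludes little for a single mimic, or for both mimics together at 4-fold or less. The simulated mimic arrays varied like the controls, while the real ones lie closer together. The recovery for both mimics together is therefore not the power of the real comparison.

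Because the tests of single mimics have so little power, probe sets were also counted by size: 2-fold or more above both controls, or below both, beside the number at which the controls differ from each other. Counts common to both mimics were set beside the product of the list sizes over the number of probe sets and beside 100 simulated sets of unchanged arrays against the same controls. The simulated mimics varied independently with the moderated spread of the controls and did not pass through the selection of the table.

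Gene lists were fixed before the data were examined: 24 lists, of which 9 had at least 5 members among the 1431 genes and 3 had none. A list member is called measured if it is among these genes. Members outside the table may have missed its selection, so their absence does not mean that the array lacked them. They cover reported miR-9 and miR-9* targets, p53 targets, apoptosis, G1/S and DNA replication, mitosis, estrogen response, interferon response, luminal, basal, mesenchymal, fibroblast and leukocyte markers, unfolded protein response, cholesterol synthesis, hypoxia, oxidative stress, one-carbon metabolism, NF-kB, immediate early genes, histones, the miRNA pathway, ribosomal proteins and housekeeping genes. For lists with 5 or more measured members, the median difference from the control mean was given with its percentile among 10000 random lists of the same size matched on mean expression in 10 bins. The percentile describes these arrays and is not a p-value. Members of all lists were counted by the 2-fold and a 1.5-fold rule.

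The genes named were chosen by a rule fixed before the data were examined. For each mimic, they are the 12 genes with the highest and the 12 with the lowest difference from the control mean that pass the test. As none passed, the places were filled by size from genes that lie beyond both controls by more than the controls differ from each other, and their values are called higher or lower. Genes with a greater difference whose controls lay further apart, such as TFF1, are therefore not among these places. Up to 4 members of each list that lie 1.5-fold or more beyond both controls were added, with TP53, CDH1, REST, NFKB1, ACTB and GAPDH where measured. For both mimics together and for the mimics against each other, 6 genes per direction were named. List members given only to show how a list is divided were named after their values were seen, as were the genes given to describe the controls.

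The alternatives were other variance priors (trended, robust), quantile normalization, median centring, leaving out the lowest 25% of probe sets by mean signal, adding 16 in place of 1, 1 probe set or the mean of all probe sets per gene, unadjusted p, other size rules, the fit without the other mimic, split controls, and leaving out each control. Both scalings were computed over the selected probe sets of the table only, not over the whole array. Counts over the probe sets at which the controls differ by under 2-fold were added after seeing the data. The planned comparison of genes with and without seed matches to each mimic was not run, because no transcript sequences were used here. Other computation used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3; figures were drawn with matplotlib 3.10.9.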

Results

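MCF-7 is an estrogen receptor-positive human breast cancer cell line. The series compared MCF-7 cells transfected with mature mimics of miR-9 or miR-9*, the products of opposite arms of one microRNA hairpin, with control MCF-7 cells, in order to look for genes that respond to each arm. RNA of the transfected cells was collected 48 h after transfection and measured on Affymetrix expression arrays. There were 4 arrays: 2 controls, 1 with miR-9 and 1 with miR-9*. The labels call the controls biological replicates and do not say whether they were mock-transfected. The table analysed here held linear signals for 2160 probe sets. The median signal was 207 on control 1, 208 on control 2, 278 with miR-9 and 292 with miR-9*. Each mimic had 1 array, so the spread of a mimic was never measured, and the number of arrays limits the precision of every value. Probe sets rather than genomic positions identify the transcripts, because no genome build was named in the sources used here.

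The 2 control arrays expressed different sets of genes. KRT8 and KRT18, keratins of luminal epithelium, had signals of 2116 and 5876 on control 1 and of 15863 and 21811 on control 2. TFF1, a classic estrogen-induced gene, stood at 151 on control 1 and 16958 on control 2. In the other direction, VIM, the mesenchymal intermediate filament protein, was 14319 on control 1 and 98.0 on control 2. The 10 genes measured of the unfolded protein response list had a median 2.49 log2 units higher on control 1 than on control 2, at the percentile 99.98 of random lists matched on expression. The 2 controls were 2-fold or more apart at 969 of the 2160 probe sets (44.9%), and the 2 mimic arrays at 25 (1.16%). Across probe sets, which are not independent replicates, Pearson's correlation of log2 signals was 0.52 between the controls and 0.98 between the mimics.

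**Figure D1:**
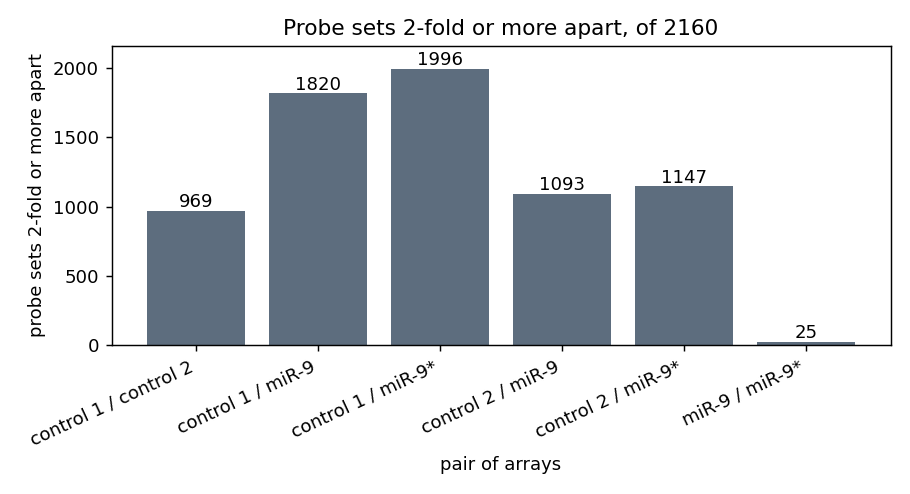
Number of probe sets at which each pair of the 4 arrays was 2-fold or more apart, of 2160 probe sets. Each bar is 1 pair of arrays: the controls were apart at 969 probe sets and the mimics at 25, while the pairs of control 1 with a mimic reached 1820 and 1996.

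The probe sets in the table were not a neutral sample of the array. In all 2160 the linear mean of both mimic arrays was at least 2-fold from control 1, with a smallest fold of 2.00009, while 1042 were under 2-fold from control 2. Any distance from control 1 therefore follows in part from how the table was made. Control 2 did not enter this condition, but the mimic values did, so distances of the mimics from control 2 are not free of it. The shares that follow are therefore no unconditioned check. Of the 1451 probe sets with a mimic mean above control 1, 1202 (82.8%) were also above control 2, and 654 (45.1%) by 2-fold. Of the 709 below control 1, 396 (55.9%) were also below control 2, and 227 (32.0%) by 2-fold.

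The comparison of miR-9 with control asked which transcripts differ in cells given the miR-9 mimic. Among genes that lay beyond both controls by more than the controls lay from each other, several interferon response genes had high values. HERC5, a ligase that attaches ISG15 to proteins, had a signal of 560 with miR-9 against 20.8 and 48.5 in the controls, a log2 difference of 4.10 ± 1.10 (standard error; 1 array against 2). Its control 1 signal is close to the lowest of that array among the selected probe sets, 15.4, so its size and rank are uncertain. OASL, an antiviral protein of the oligoadenylate synthetase family, stood at 1126 against 63.1 and 84.3, a difference of 3.93 ± 1.04. IFIT1 and IFIT3, which act on viral RNA, lay 3.25 ± 1.03 and 3.26 ± 1.20 above the control mean. IFIT3 had a signal of only 13.4 on control 2, so its size is uncertain as well. Of 30 interferon-stimulated genes on the list, 8 were in the selected table. Of these 8, 5 lay 2-fold or more above both controls and none lay 2-fold below. The list median was 2.76, higher than in any of 10000 random lists of matched expression, whose median was 0.79. The other 3, ISG15, RIGI and IFIH1, had similar signals on control 2 and with miR-9, at 3086 and 3484 for ISG15, and were low on control 1. With limma, none of the 8 passed over all probe sets. Adjusted over the list alone, 3 had an adjusted p under 0.05: OASL and HERC5 (adjusted p = 0.0334 each) and IFIT1 (adjusted p = 0.0455). These rest on 1 miR-9 array, assumed to vary like the controls, and on errors largely pooled over all probe sets. They also rest on a table conditioned on control 1, so they are not called changes.

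Outside that list, the 12 highest named genes with miR-9 included MIR100HG, a long noncoding host transcript of microRNAs (signal 142 against 15.4 and 6.00), CPEB1, a regulator of mRNA polyadenylation (log2 difference 3.15 ± 1.21), and SARNP, an mRNA export factor (2.75 ± 1.03). RFESD, ZMYM6, LPXN, HLF and SPTLC1, a subunit of serine palmitoyltransferase, followed with differences between 2.37 and 2.43. HLF, at 21.9 on control 1, and ZMYM6, at 29.3 and 19.2 in the controls, had low control signals, so their sizes and ranks are uncertain. The lowest values belonged to OPN3, an opsin (-3.11 ± 1.08), ANKRD36B (-3.05 ± 1.17), PKIB, an inhibitor of protein kinase A (-2.96 ± 1.17), LRP8, a lipoprotein receptor (-2.94 ± 1.07), and PCLAF, a partner of the replication clamp PCNA (-2.92 ± 1.03). ANKRD36B and LRP8 had signals of 22.8 and 25.7 with miR-9, close to the lowest of that array among the selected probe sets, 15.8. Their sizes and ranks are therefore uncertain. GLCCI1, the maintenance methylation factor UHRF1, the actin-binding thymosin TMSB10, PSMA3-AS1, AIF1L, the protease PRSS23 and FAM210B lay between -2.55 and -2.14.

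In all, 530 probe sets lay 2-fold or more above both controls with miR-9 and 207 lay below both. No probe set passed limma at an adjusted p of 0.05, and the smallest adjusted p was 0.759. At an unadjusted p under 0.05 there were 17 higher and 14 lower, but 11 and 51 after quantile normalization and 6 and 32 after median centring. The share of higher values, 71.9%, depended on array scaling: it was 35.5% after quantile normalization (184 above, 335 below) and 31.6% after median centring (144 above, 311 below). Over all probe sets the median shift from the control mean was 0.75 log2 units with miR-9 and 0.85 with miR-9*.

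The comparison of miR-9* with control asked the same of the other arm. Of the 12 genes named per direction by the same rule of size, 9 of the highest and 9 of the lowest were also named with miR-9. HERC5 lay 3.40 ± 1.10 log2 units above the control mean, CPEB1 3.18 ± 1.21 and OASL 3.15 ± 1.04. MIR100HG had a signal of 170 with miR-9*. Its control 1 signal was the lowest of that array among the selected probe sets. The size of its difference and its rank are therefore not interpretable with either mimic. CCN2, a secreted matricellular protein, lay 2.92 ± 1.11 above control, and the helicase ASCC3 and ANKRD12 lay 2.58 ± 1.12 and 2.47 ± 1.03 above; these were among the 12 highest with miR-9* and not with miR-9. IFIT3, IFIT1, SARNP, ZMYM6 and RFESD lay between 2.46 and 2.91, where the sizes of IFIT3 and ZMYM6 rest on low control signals. The lowest were OPN3 (-3.35 ± 1.08), PCLAF (-3.04 ± 1.03), PKIB (-2.99 ± 1.17), GLCCI1 (-2.53 ± 1.16) and PRSS23 (-2.48 ± 1.04). TMSB10, LRP8, AIF1L, UHRF1 and 3 genes that were not among the 12 lowest with miR-9, GINS2 of the replicative helicase, the noncoding RNA TINCR and fatty acid synthase FASN, lay between -2.37 and -2.10.

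The interferon list behaved alike by size: 5 of 8 members lay 2-fold above both controls with miR-9*, and the median was 2.24, above all 10000 random lists. Adjusted over the list alone none passed, with a smallest adjusted p of 0.0813. By the 2-fold rule 658 probe sets lay above both controls and 209 below. No probe set passed limma over all probe sets (smallest adjusted p 0.703), and 19 higher and 14 lower had an unadjusted p under 0.05, but 10 and 72 after quantile normalization and 6 and 39 after median centring. The share of higher values was 75.9%, and it was 37.5% after quantile normalization and 30.6% after median centring. As with miR-9, the scaled values come from selected probe sets and cannot tell array scaling from the selection.

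Beyond the interferon genes, immediate early genes, the first transcripts made after a growth or stress signal, had list medians above the control mean with both mimics that did not stand apart from control 2. Of 9 measured, 4 lay 2-fold or more above both controls with each mimic and 5 by 1.5-fold, among them ATF3, CCN1, CCN2, FOSL1 and KLF6. ATF3, a stress-induced transcription factor, had signals of 9452 with miR-9 and 9745 with miR-9* against 3887 and 89.9 in the controls. CCN1, a matricellular protein, had 4253 and 4651 against 1085 and 149. FOS, JUN and EGR1 were low on control 1 and, with signals of 578, 1303 and 421, near or above the mimic arrays on control 2, and DUSP4, a MAP kinase phosphatase, lay between the controls at 345 and 333 against 1015 and 183. The list medians were 1.77 with miR-9 and 2.12 with miR-9*, at percentiles 99.99 and 100, and the controls also differed in this list by 1.28 (percentile 98.8). Against control 2 alone the medians were 0.91 and 1.04, at percentiles 79.7 and 81.6, where random lists had 0.55 and 0.59.

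Of 8 measured genes of G1/S and DNA replication, 4 lay 1.5-fold or more below both controls with each mimic. CDT1, which loads the replicative helicase, was 269 with miR-9 and 201 with miR-9* against 773 and 883 in the controls. GINS2 was 197 and 178 against 619 and 1233. RRM2, a subunit of ribonucleotide reductase, was 179 and 141 against 441 and 3527. By the 2-fold rule these were 3 with miR-9 and 4 with miR-9*, the latter with the helicase subunit MCM4. CDC6, MCM3 and MCM5 did not lie 1.5-fold beyond both controls, and CDK6, a G1 kinase, lay above both at 985 and 1378 against 532 and 335. The list medians were -0.90 with miR-9 and -1.08 with miR-9*, at percentiles 1.10 and 0.43, where random lists had medians of 0.70 and 0.79. The median of control 1 minus control 2 was 0.22 in this list, but differences of opposite sign cancel in it. Single members ran from -3.00 for RRM2 to 1.44 for CDC6, so the controls did not agree on these genes.

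**Figure D2:**
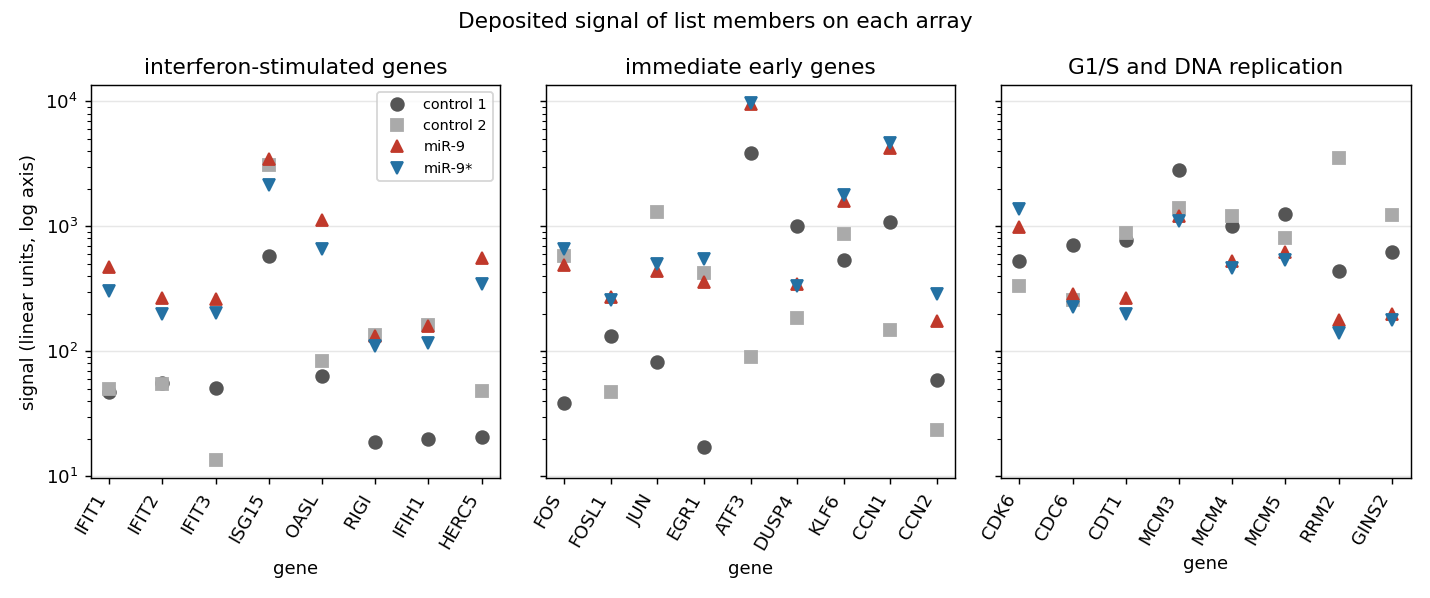
Signal (linear units, logarithmic axis) of each measured member of 3 gene lists on each of the 4 arrays, 1 symbol per array. IFIT1, IFIT2, IFIT3, OASL and HERC5 lie above both controls on both mimic arrays, as do ATF3 and CCN1, while CDT1, RRM2 and GINS2 lie below both.

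Of 5 estrogen-responsive genes measured, 3 had low values, against controls that were themselves far apart. PKIB, STC2, a secreted glycoprotein, and TFF1 lay 2-fold below both controls with both mimics. IGF1R, a growth factor receptor, lay above both at 1363 and 1245 against 616 and 1138, by less than 1.5-fold from control 2, and NRIP1 lay between them. TFF1 was 66.1 with miR-9 and 52.0 with miR-9*. The list medians were -1.79 and -1.83 (percentiles 0.125 and 0.075), and control 1 lay 1.68 log2 units below control 2 in the same list (percentile 0.39). Against control 2 alone the medians were -3.22 and -2.77 (percentiles 0.01 and 0.02), and against control 1 alone -1.18 and -1.29 (percentiles 6.71 and 3.73). KRT8 and KRT18, the 2 luminal markers measured, lay below both controls with both mimics, at 871 and 2036 with miR-9 and 668 and 1900 with miR-9*.

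Reported miR-9 targets had medians near those of random lists against the control mean. Of 30 on the list, 6 were measured, and their median was 0.49 with miR-9 (percentile 35.02) and 0.71 with miR-9* (percentile 44.3). Against control 1 alone the medians were 1.01 and 1.39 (percentiles 52.3 and 95.8), and against control 2 alone 0.49 and 0.76 (percentiles 43.4 and 53.4). UHRF1 lay below both controls, at 109 with miR-9 and 115 with miR-9* against 428 and 628. SIRT1, a deacetylase, lay above both, at 605 and 729 against 261 and 259, and so did CDK6. ONECUT2, HES1 and CXCR4 lay between the controls or within 1.5-fold of one of them. None of the 5 reported miR-9* targets was among the genes of the table. CDH1, REST, NFKB1, TP53, ACTB and GAPDH were not analysed here.

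p53 target genes were split. GADD45A, a DNA damage-inducible gene, ZMAT3 and the nuclease AEN lay 2-fold above both controls with both mimics, GADD45A at 5976 and 6083 against 2346 and 263, while SFN, the 14-3-3 sigma gene, lay below both at 879 and 844 against 2120 and 6167. The medians of the 6 members were 0.69 and 0.79 (percentiles 49.4 and 51.5). They were 0.17 and 0.27 against control 2 alone (percentiles 24.3 and 25.8) and 1.15 and 1.33 against control 1 alone (percentiles 87.1 and 96.0). The apoptosis regulators BAK1 and XIAP lay above both controls with both mimics, by 1.5-fold or more, 2 of 4 members measured. MCL1 and CFLAR did not reach that distance. Over all 2160 probe sets, 40.1% lay as far above both controls with miR-9 and 43.8% with miR-9*, so 2 of 4 is near that share. In the NF-kB list, the cytokine IL6 stood at 1081 with miR-9 and 1397 with miR-9* against 273 and 24.2, and REL lay 1.5-fold above both controls with miR-9* and less than that with miR-9, a difference between mimics that passed no test.

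Metabolic lists were small. All 3 cholesterol synthesis genes measured, SQLE, MSMO1 and INSIG1, lay below both controls with both mimics, MSMO1 at 366 and 397 against 865 and 869. The pentose phosphate enzyme PGD, the single oxidative stress gene measured, was 740 and 652 against 3016 and 2462. Of 5 one-carbon and serine genes, MAT2A, which makes S-adenosylmethionine, lay below both controls and PHGDH, PSAT1, PSPH and SHMT2 lay between them. The medians of that list were 0.22 and 0.04 (percentiles 23.4 and 19.3) with a control difference of 2.70, and they became -0.20 and -0.45 after median centring. They were 1.57 and 1.39 against control 2 alone (percentiles 94.0 and 90.6) and -1.13 and -1.23 against control 1 alone (percentiles 11.4 and 9.16). None of the 4 hypoxia genes lay 1.5-fold beyond both controls.

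Of 10 unfolded protein response genes, ATF3 and PPP1R15A lay 2-fold above both controls and the chaperone genes such as HSPA5, CALR and PDIA4 lay between them. The medians were -0.14 and -0.22 (percentiles 9.19 and 8.04). They were 1.07 and 0.95 against control 2 alone (percentiles 86.6 and 76.4) and -1.34 and -1.26 against control 1 alone (percentiles 0.205 and 2.175). Of 5 mesenchymal markers, ZEB1 lay above both controls and CD44 and CAV1 below both. VIM and S100A4, the latter also the single fibroblast marker measured, lay between the controls. The medians were -0.72 and -0.80 (percentiles 7.14 and 5.88), and the controls differed by 4.06. The medians were 1.75 and 1.67 against control 2 alone (percentiles 96.1 and 94.1) and -1.47 and -1.65 against control 1 alone (percentiles 0.955 and 0.195). Of 2 basal markers, CAV1 lay below both controls and LAMB3 between them. The histone gene H2BC12 lay below both controls and the Argonaute gene AGO4 above both, with AGO1 between. The 3 mitotic genes measured, CDK1, CENPE and HMMR, and the housekeeping gene TFRC did not lie 1.5-fold beyond both controls. No ribosomal protein gene and no leukocyte marker was among the genes of the table.

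**Figure D3:**
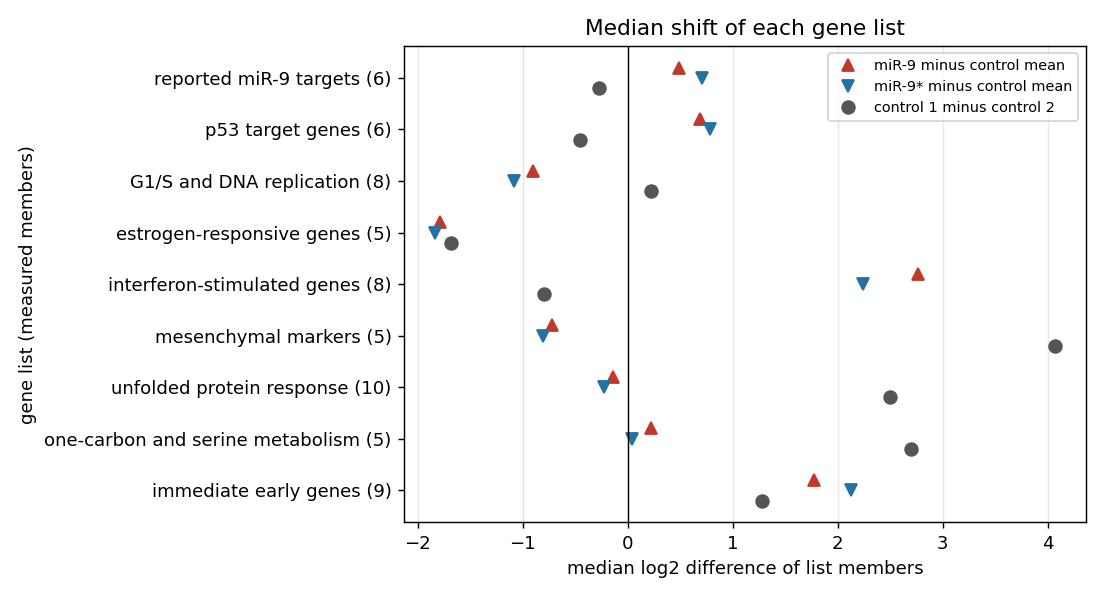
Median log2 difference of the 9 gene lists with 5 or more measured members, for miR-9 and miR-9* minus the control mean and for control 1 minus control 2. The interferon list is at 2.76 and 2.24 with the mimics and -0.80 between the controls, while the mesenchymal list differs more between the controls (4.06) than with either mimic.

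Taking the 2 mimics as 1 transfected group of 2 arrays against the 2 controls addressed what the cells had in common whichever arm they received. Different treatments stand as replicates in this fit, so its smaller errors come in part from the likeness of the mimic arrays. High values among named genes were those of HERC5 (log2 difference 3.75 ± 0.58), OASL (3.54 ± 0.44), CPEB1 (3.16 ± 0.75), IFIT3 (3.09 ± 0.73) and IFIT1 (2.95 ± 0.38). MIR100HG, also named, has no interpretable size, and the sizes of HERC5 and IFIT3 rest in part on low control signals. The lowest were OPN3 (-3.23 ± 0.48), PCLAF (-2.98 ± 0.32), PKIB (-2.98 ± 0.67), LRP8 (-2.62 ± 0.50), GLCCI1 (-2.54 ± 0.64) and PRSS23 (-2.32 ± 0.38). LRP8 had low signals with both mimics, 25.7 and 40.8. No probe set passed limma, where the smallest adjusted p over all probe sets was 0.0947. At an unadjusted p under 0.05 there were 732 higher and 233 lower, but 324 and 365 after quantile normalization and 228 and 320 after median centring. Both scalings used the selected probe sets alone, and these counts treat the different mimics as replicates. The count depended on the controls: without control 1, 1626 probe sets passed at an adjusted p of 0.05, and without control 2, 2159 passed, the latter against the array on which the table was conditioned.

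Set directly against each other, the mimics differed mostly in 1 direction. No probe set was 2-fold higher with miR-9 than with miR-9*, and 25 were 2-fold lower. The lowest named genes were N4BP2L2 (217 with miR-9 and 604 with miR-9*, log2 difference -1.47 ± 1.24), the RNA-binding protein genes RBM15 (-1.41 ± 1.29) and HNRNPD (-1.39 ± 1.19), the noncoding RNA FTX (-1.36 ± 1.21), TBRG1 (-1.23 ± 1.22) and PSMA3-AS1 (-1.22 ± 1.21). The highest named genes were OASL (0.78 ± 1.20), MAP2K6, a MAP kinase kinase (0.69 ± 1.20), IFIT1 (0.62 ± 1.19), IFIT2 (0.42 ± 1.19), RNF19B (0.42 ± 1.19) and CDT1 (0.42 ± 1.19). All these differences were within 2 standard errors, which come from the controls; no probe set passed limma, and 0 had an unadjusted p under 0.05.

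Probe sets beyond both controls were largely shared between the mimics. Above both controls by 2-fold, 467 were common to the 530 with miR-9 and the 658 with miR-9*, where independent lists of those sizes would share 161. Below both, 169 were common to 207 and 209, where independent lists would share 20.03. None lay above both controls with 1 mimic and below both with the other. Unchanged arrays simulated against the same 2 controls had shorter lists, on average 116 per mimic in each direction, and shared 8.43 above and 7.72 below. The simulated mimics were drawn independently with the moderated spread of the controls, and without the selection of the table. They are therefore no background for these selected probe sets. When each mimic was set against a different control, 574 or 579 were shared above and 197 or 198 below, where independent lists would share 477 or 501 and 81.3 or 87.6. With miR-9 against control 1 and miR-9* against control 2, 41 lay above with miR-9 and below with miR-9*, and 161 the other way; with the controls exchanged these were 159 and 62. Each split of the controls leaves 1 array per comparison, so part of the excess may come from the shared controls, and part from a table conditioned on the mean of both mimics.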

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

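The count over probe sets at which the controls differ by under 2-fold was chosen after the data were seen; the other alternatives were planned. The adjusted limma counts stayed at 0 for miR-9, miR-9* and the 2 mimics against each other under both other variance priors, both scalings, the signal filter, the larger added constant and 1 probe set per gene, and for both mimics together under the same settings. At an unadjusted p under 0.05 the counts were 31, 33 and, for both mimics together, 965. Leaving out a control gave 1626 to 2159 for both mimics together, because the spread between the controls was then gone; for a single mimic it leaves no residual degree of freedom and so a value with no test. By the 1.5-fold rule 866 probe sets lay above and 311 below both controls with miR-9, and 840 above and 280 below with both mimics. Quantile normalization gave 184 above and 335 below with miR-9 and 203 and 339 with miR-9*, and median centring gave 144 and 311 with miR-9 and 133 above with miR-9*. Both scalings used only the selected probe sets, so they may also remove a shift set by the selection. Leaving out each control gave 796 to 1179 above and 297 to 641 below with miR-9, and 873 to 1359 above and 274 to 637 below with miR-9*. Where the controls differ by under 2-fold (1191 probe sets), 409 lay above and 151 below with miR-9, and 516 and 145 with miR-9*.

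List medians follow for miR-9 and then miR-9*. Quantile normalization moved the reported miR-9 targets to 0.17 and 0.20, G1/S genes to -1.08 and -1.47, interferon genes to 1.95 and 1.40, and one-carbon genes with miR-9* to -0.0199. Median centring moved the reported targets to 0.0638 and 0.21, p53 targets to 0.26 and 0.29, G1/S genes to -1.32 and -1.57 and one-carbon genes to -0.20 and -0.45. Leaving out each control gave these ranges: reported targets 0.49 to 1.01 and 0.76 to 1.39; p53 targets 0.17 to 1.15 and 0.27 to 1.33; G1/S genes -1.26 to -0.80 and -1.49 to -0.98; estrogen-responsive genes with miR-9 -3.22 to -1.18; mesenchymal markers -1.47 to 1.75 and -1.65 to 1.67; unfolded protein response -1.34 to 1.07 and -1.26 to 0.95; one-carbon genes -1.13 to 1.57 and -1.23 to 1.39; and immediate early genes with miR-9* 1.04 to 2.10. The sign of the mesenchymal, unfolded protein response and one-carbon medians thus depended on which control was used; for the other lists the cause of the movement was not tested. Among the 133 values of named genes, 0 reversed under quantile normalization; median centring, which shifts all genes of an array alike by less than these differences, and leaving out a control, for genes named because they lie beyond both, could not reverse any. The planned seed match comparison was not run. No paired analysis was possible because the mimics had 1 array each and share fewer than 2 replicate numbers with the controls. Signals near the low end of each array, whose minima over the selected probe sets were 4.18 to 18.4, bound the folds of weakly expressed transcripts.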

Other observations

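The genes in this and the next paragraph were chosen after their values were seen. Among the 25 probe sets 2-fold lower with miR-9 than with miR-9* were those of LUC7L3, HNRNPDL and HNRNPA3. LUC7L3, a splicing factor, had a signal of 293 with miR-9 and 608 with miR-9*, against 918 and 1355 in the controls. HNRNPDL had 340 and 729 against 1193 and 994, and HNRNPA3 had 145 and 293 against 512 and 458. Of the 25, 15 also lay below both controls with miR-9. For PCBP2, one probe set had 95.8 and 216, while another had 250.1 and 249, so the probe sets of 1 gene did not move together. At 1.5-fold, 93 probe sets were lower with miR-9 than with miR-9* and 11 were higher. Whether this follows from the sequence of the mimics was not tested.

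STC1, a secreted glycoprotein, had 48.8 with miR-9 and 42.4 with miR-9* against 370 and 1472 in the controls at one of its probe sets. All 7 probe sets of CD44, the hyaluronan receptor, were lower than both controls with both mimics, with log2 differences from the control mean between -1.81 and -1.15. The nuclear receptor NR4A3, at one of its probe sets, had 1049 and 1230 against 446 and 38.4.

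Of the tests that follow, those of array scaling and of table selection for the controls, of different cells in either control and of double-stranded RNA for the interferon genes, and of a shared step for the mimics were chosen after the result was seen. For the difference between the controls, the first pattern, array scaling is argued against by the 918 probe sets that stayed 2-fold apart after quantile normalization, against 27 between the mimics. Selection on control 1 is argued against for the largest distances only. Control 2 lay 8-fold or more from miR-9 at 154 probe sets, where control 1 did at 17. For the 969 probe sets 2-fold apart between the controls the test cannot decide. Control 1 was at least 2-fold from the mimic mean in every row, while control 2 was under 2-fold from it at 1042. The array labelled control 2 lay 8-fold or more from all 3 other arrays at 68 probe sets, against at most 9 for any other array. It was below them at 64 of these and above them at 4. This split follows in part from the selection: the highest signal among control 1 and the mimics was never below 100.1, with no such bound on control 2. Transcripts high on control 2 alone may therefore be missing. The count of 68 goes with control 2 and the other 3 arrays coming from different cells, and does not say which side departs. With signals below 100 set to 100 the counts were 22 and 4. Among the transcripts were CGA, the glycoprotein hormone alpha chain (13150 on control 1, 4354 and 4423 with the mimics, 15.4 on control 2), PLS3 (1724, 3372, 3616 and 9.60) and TFF1 in the other direction. Control 1 minus control 2 had a median of -1.68 for the 5 estrogen-responsive genes and of 4.06 for the 5 mesenchymal markers. Against control 2 alone the mimic medians went the same ways, at -3.22 and -2.77, and at 1.75 and 1.67. In these lists control 2 had the values nearer to an estrogen receptor-positive line, so its distance does not mark it as the departing array. Whether any array departs from its label, and which, stays open, and no biological explanation was tested. Until that is settled, the control mean may average arrays from different cells, and every difference from it carries this limit.

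The second pattern is the interferon-stimulated genes. Array scaling is argued against by a list median of 1.95 with miR-9 after quantile normalization. Different cells in control 1 alone are argued against by the median from control 2, which was at least 2.23 with both mimics where random lists had 0.93. Different cells in control 2 stay open, because they would themselves shift that value, and the median from control 1 (at least 2.49, random lists 1.09) comes from a table selected on control 1. A response to transfected double-stranded RNA of any sequence may account for 5 of 8 members lying above both controls with both mimics, and it cannot be told apart from an effect of the mimics' sequences, because no mock or scrambled mimic array was analysed here.

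The third pattern is the likeness of the mimic arrays. For higher probe sets, selection on the mean of both mimics would still admit transcripts raised by 1 mimic alone, yet 3 of 323 probe sets 3-fold above control 1 with 1 mimic were under 1.5-fold with the other. For the 709 lower probe sets the selection itself bounds the likeness: the less lowered mimic kept at most 72.1% of the control 1 signal, so selection and a shared effect cannot be told apart there. A shared step such as transfection or array handling could also leave only 25 probe sets 2-fold apart, and it cannot be told apart from shared effects of the 2 arms, because each mimic has 1 array and no batch labels were given.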
